A study of Mus musculus with 3 samples.

How the data were processed

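Total RNA of aortas was amplified, labelled and hybridised to 3 two-colour Agilent arrays, per the labels' protocols. Each array held 1 individual sample labelled Plk1(+/-) in Cy5 and the same pool of 3 wild-type samples in Cy3, and no array had the dyes the other way round. Dye and genotype therefore cannot be separated. The labels name the 3 samples as biological replicates. The pool counts as 1 control sample, and testing the ratio against 0 leaves out the control's own spread. The growth protocol in the labels describes embryonic stem cells, while the tissue label is aorta, and the tissue label was followed.

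Spot intensity values in the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1, per the file headers, and the mean signals used here are neither background-subtracted nor normalized. Per the file headers, the deposited log ratio is a log10 ratio of processed Cy5 over processed Cy3, after background subtraction and dye normalization within the array. It equalled the log10 ratio of both processed signals within 0.001 for 83.5%, 84.6% and 85.3% of spots on the 3 arrays. The authors' series values are log2, for 28817 of 41174 probes. Set against the scanner files' log ratio in log2, its columns had slopes of 0.997, 1.00 and 0.998 and medians of -0.02, -0.0052 and -0.03, so scale and direction were known and its centring step was not stated. Spike-in controls gave slopes of observed against expected log ratio of 0.793, 0.815 and 0.823, per the file headers, so ratios are somewhat compressed. The intercepts of that fit were -0.381, -0.313 and -0.271 in log10. Spike-ins expected at a log ratio of 0 thus read lower in Cy5 on each array. Most calls below are lower too, but they come from a separate normalization with control spots at weight 0. Most of them are also on saturated probes. Neither the cause of the intercepts nor a link with the calls was tested.

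Mean signals were background-corrected with normexp (offset 50) on all spots and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. Control spots and spots marked as non-uniform or population outliers (136, 109 and 100 per array) were then left out, and spots of 1 probe were averaged. A probe was kept if it was well above background in either dye on at least 2 of 3 arrays. The probe with the highest mean intensity stood for each gene, and probes without a gene symbol stayed on their own, which gave 22140 features, 17707 of them with a symbol. Median mean signals were 163, 165 and 156 in Cy3 and 335, 357 and 337 in Cy5, against local backgrounds of 52 to 53 and 70 to 71.

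Gene names in the files follow an old design annotated on mm7. Names were updated through a gene listing of assembly GRCm38.p6, used only for names and for the order of neighbouring genes: 22951 probes matched by accession, 6659 had a current symbol, 3109 matched a synonym and 8455 kept the name in the files. Probe positions are those of the files in mm7. Exon and UTR positions were not analysed here. Of 140 genes that the naming rule took, 52 had a further kept probe, and for 10 a further probe had the opposite sign.

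Each feature's log2 ratio was tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features. Gene lists, 28 in all, were fixed before the data were examined. The 27 of them other than the sex chromosome genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it. Members were also counted past the gene test over all genes and, for members without a saturated spot, adjusted over the list alone. Fry asks whether a list's genes move on balance one way, without comparing them with other genes. The arrays are compared through 1 shared pool, which alone gives correlated ratios.

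Genes were named by a rule set before the data were examined: Plk1; the 12 largest mean rises and 12 largest mean falls past the adjusted threshold with 1 sign on all arrays and a plain gene symbol; up to 4 measured members of each list with the smallest unadjusted p; and the sex chromosome genes. Only 6 genes met the rule for rises. For falls, 10 of the 12 were saturated in both dyes and have no fold, so the 12 largest falls among the 22 passing genes without a saturated spot are given as well, a step chosen after seeing the data. Where Cy5 alone was saturated, the true Cy5 signal may be higher than the one read, so a fall may be smaller than read or absent. Where both dyes were saturated, the ratio has no bound. Saturated genes are therefore given without a fold.

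On simulated ratios for 21611 features with 3 arrays, the gene test recovered 0, 32, 46 and 49 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 6 false calls, and the list test called the 1 list shifted by 0.5 out of 27. The simulated ratios were drawn independently for each gene and array, without a shared pool, a dye effect or correlated genes. They check the steps of the tests and give no error rate for these data. Alternatives were: no background correction, offset 16, Agilent's own log ratio, the authors' series table, median centring, scaling between arrays, no filter or a stricter filter on dim probes, outlier spots kept, the mean of a gene's probes, each probe alone, an intensity trend, array weights, each sample left out, other thresholds (0.01, 0.1, and a log2 change of at least 1), an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.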

Results

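RNA of mouse aortas was compared on 3 two-colour oligonucleotide arrays of 1 slide. On each array, RNA of a single aorta labelled Plk1(+/-) carried Cy5, and RNA of a pool of 3 wild-type aortas carried Cy3. Plk1 encodes polo-like kinase 1, a kinase that drives mitosis and cytokinesis. The animals were 3 to 5 months old and of a mixed 129/CD1 background. The question was which transcripts of the vessel differ when 1 of both Plk1 alleles is lost. Probe signal was well above background for 66.0%, 69.0% and 68.0% of probe spots in Cy3 and for 80.3%, 77.0% and 80.8% in Cy5 on the arrays of samples 1, 2 and 3. The number of arrays limits the precision. All log2 ratios below are the labelled sample over the pool, so a negative value is a lower signal in the sample labelled Plk1(+/-).

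No lower signal of Plk1 itself was detected in the samples labelled Plk1(+/-). Its log2 ratio was -0.06, -0.08 and 0.42 in samples 1, 2 and 3, a mean of 0.10 ± 0.28 (SD, n = 3) with a limma adjusted p of 0.705. Its 1 probe lies on chromosome 7 at 118093971 to 118094030 of mm7, and its signal was above background in both dyes on all 3 arrays. The labels do not say which part of the allele was interrupted, so the probe may lie outside it and then checks nothing. Directions below therefore refer to samples by their label. Without sample 3 the Plk1 mean turned to -0.07.

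Among genes past the adjusted threshold on probes without a saturated spot, Cish had the largest mean difference. It encodes an SH2-domain protein that dampens cytokine receptor signalling. Cish fell by 3.15 ± 0.37 on the log2 scale (SD, n = 3; limma adjusted p = 0.00926), 8.89-fold lower, with -3.58, -2.96 and -2.91 in the 3 samples. Rab7b, a small GTPase of endosomal transport, had the next largest fall among these, at -1.82 ± 0.10 (adjusted p = 0.00709). Rasd1, a Ras-related GTPase induced by glucocorticoids, had the largest rise among these, at 1.56 ± 0.36 (adjusted p = 0.0467), and was higher in all 3 samples. The probe of Cish lies on chromosome 9 at 107031313 to 107031372, that of Rab7b on chromosome 1 at 131608159 to 131608218, and that of Rasd1 on chromosome 11 at 60045278 to 60045337, all in mm7. Without saturated features, an alternative chosen after seeing the data, the adjusted p-values were 0.162 for Cish and Rab7b and 0.223 for Rasd1, so the calls ended while the ratios stayed. Over all alternatives they ran from 0.00368 to 0.815 for Cish, 0.0034 to 0.162 for Rab7b and 0.0224 to 0.707 for Rasd1, with the highest of Cish and Rasd1 under an intensity trend. The Cish call also ended without sample 2 (0.154) and without sample 3 (0.0704), that of Rab7b without either, at the same values, and that of Rasd1 without sample 1 (0.0836), sample 2 (0.218) or sample 3 (0.0831).

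Other genes that fell on unsaturated probes included Ccdc68 (-1.38 ± 0.27), the insulin-like growth factor binding protein gene Igfbp2 (-1.32 ± 0.26), the red cell anion exchanger gene Slc4a1 (-1.29 ± 0.08), Fndc5 (-1.27 ± 0.14), the matricellular gene Ccn1 (-1.27 ± 0.25), Lrtm1 (-1.10 ± 0.23), Ocel1 (-1.05 ± 0.09), Phlda1 (-1.05 ± 0.02), the phosphoinositide 3-kinase subunit gene Pik3r1 (-1.01 ± 0.21) and Slx1b (-0.96 ± 0.17). Their adjusted p-values lay between 0.0103 for Slc4a1 and 0.0488 for Pik3r1. Beside Rasd1, the genes that rose were Nyap1 (1.15 ± 0.21), the cation channel gene Trpm2 (1.05 ± 0.10), the actin-regulator gene Cyfip2 (1.00 ± 0.12), the purine salvage gene Hprt (0.96 ± 0.14) and the sodium-proton exchanger gene Slc9a7 (0.84 ± 0.09). Their adjusted p-values lay between 0.0186 for Trpm2 and 0.0355 for Nyap1. Without saturated features the genes of this paragraph had adjusted p-values between 0.162 (Slc4a1) and 0.223, and 0 passed. A second probe of Slx1b read -0.16, and 3 further probes of Pik3r1 read between -0.63 and -0.41.

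**Figure D1:**
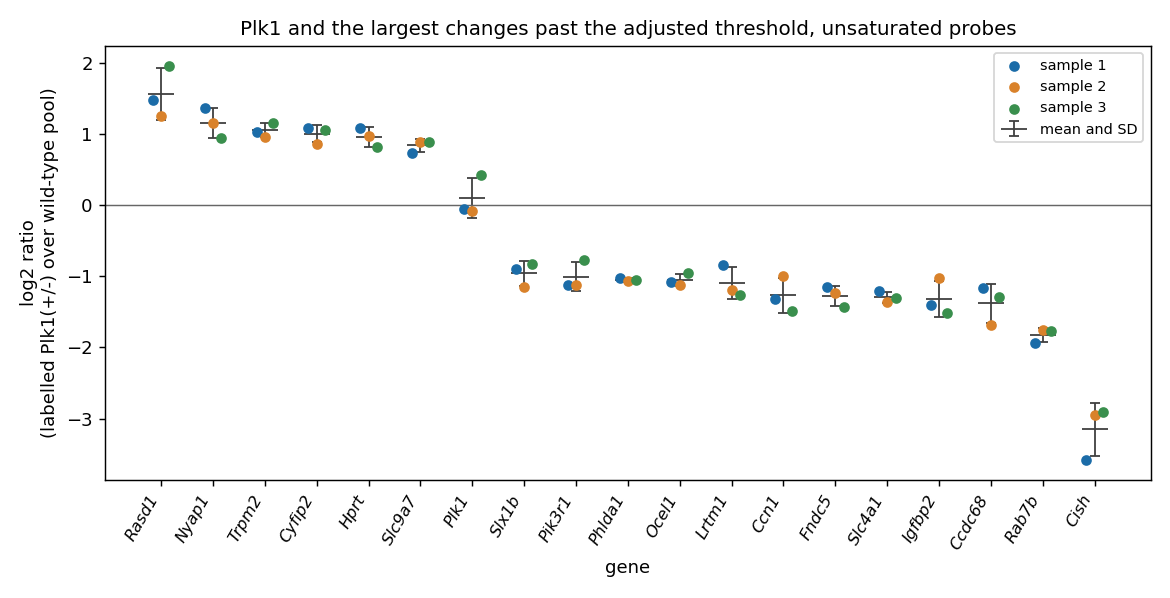
Log2 ratio of the labelled sample over the wild-type pool (vertical axis) for Plk1 and for the genes past the adjusted threshold with the largest rises and falls on probes without a saturated spot (horizontal axis). Points are the 3 samples, and the bar is the mean with its SD. Cish sits between -3.58 and -2.91, while Plk1 lies on both sides of 0.

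Over all 22140 features, limma called 204 at an adjusted p under 0.05, 8 higher and 196 lower in the labelled samples. Of these, 172 were on probes with a saturated spot, all 172 lower, and 32 were on probes without one, 8 higher and 24 lower. With saturated features left out, limma called 0 of 21611 features (lowest adjusted p 0.162), so 0 of the 32 stayed called, and 3827 had an unadjusted p under 0.05, 2002 higher and 1825 lower. With an intensity trend in the variance limma also called 0, with 4210 at an unadjusted p under 0.05. The count was 175 without sample 1, and limma called 0 without sample 2 and 0 without sample 3, with 1988 and 3113 at an unadjusted p under 0.05. Median centring in place of loess gave 9813 calls, 7169 higher and 2644 lower, which is 73.1% higher against 3.92%, with the median over all features at 0.23 against 0.04.

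Among the 12 genes with the largest falls past the test, 10 had both dyes saturated on all 3 arrays: Cox6a1, Acadvl, Myl6, Gsn, Dbi, Cox8a, Chchd2, Hadhb, Cox4i1 and Ndufb8. A spot at the scanner's limit in both dyes has no measured fold, so none is given. Cy5 was saturated on 574, 627 and 595 of 43379 probe spots and Cy3 on 66, 104 and 67. An unsaturated second probe of Ndufb8, a complex I subunit gene, read 0.04 ± 0.02 (SD, n = 3).

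**Figure D2:**
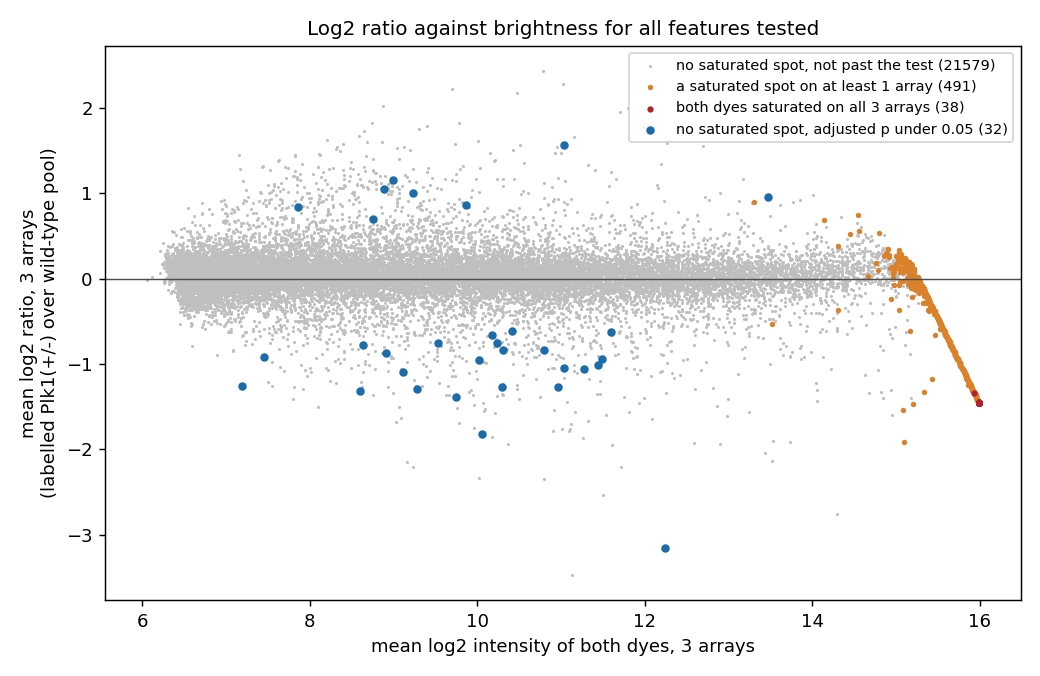
Mean log2 ratio over 3 arrays (vertical axis) against the mean log2 intensity of both dyes (horizontal axis) for all 22140 features. Orange and red points have a saturated spot and run down a line at the brightest end, to the 38 features with both dyes saturated on all 3 arrays. The 32 blue points are the called features without a saturated spot.

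Gene lists fixed before the data were examined were then set against all other genes. Medians below are over members without a saturated spot, given for samples 1, 2 and 3. Camera's adjusted p is over all members tested, with its preset correlation unless stated. A list's median under an alternative, such as median centring, is over all members which that alternative tested. Over all 21611 unsaturated features, 17.7% had an unadjusted limma p under 0.05. Each count of list members at that level below is to be set beside this share. Camera called 23 of 27 lists, 5 higher and 18 lower. With an estimated correlation camera called 0 of 27, and without saturated features as well, where 0 lists had an unadjusted p under 0.05 (lowest 0.0824). Fry called 5, all lower: the respiratory chain, oxidative stress, white fat, brown fat and red cell lists, and 0 without saturated features, where 6 had an unadjusted p under 0.05. With median centring 9 of the 27 were called, 8 of these calls in the same direction and the endothelium list in the other, and leaving out saturated features left 19.

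Genes of the smooth muscle contractile apparatus were lower in all 3 samples. All 19 members without a saturated spot fell in the test adjusted over the list alone, and all 19 were negative on every array, with medians of -0.36, -1.13 and -0.79. Myh11, the smooth muscle myosin heavy chain, fell by 1.31 ± 0.55 (SD, n = 3), Pdlim3 by 1.28 ± 0.60, the vinculin gene Vcl by 0.49 ± 0.18 and the smoothelin gene Smtn by 0.40 ± 0.13, in the same test. Markers of other cell types also differed in these samples, with medians of 0.16, 1.5 and 1.86 for lymphocytes, -0.75, -0.89 and -2.70 for skeletal muscle and -0.28, -0.42 and -0.32 for adventitial fibroblasts. Tpm1 and Des, also made in striated muscle and chosen after their values were seen, read -0.71, -0.77 and -2.81 and -0.49, -0.59 and -1.40. Over all genes, 6 of 26 members passed, all on saturated probes (Acta2, Myl6, Myl9 and Flna among the saturated). Camera gave an adjusted p of 5.36e-20 (1.65e-27 to 7.92e-08 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation.

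Matrix genes were lower in the same samples. Of 27 unsaturated collagen and other matrix genes, 22 fell adjusted over the list alone and 0 passed over all genes, with medians of -0.48, -0.83 and -0.51. The fibronectin gene Fn1 read -0.93 ± 0.21 (SD, n = 3), Col5a1 -0.73 ± 0.21, Col6a1 -0.67 ± 0.16 and Col8a1 -0.64 ± 0.13. Markers of adventitial fibroblasts, which make matrix, had medians of -0.28, -0.42 and -0.32, and 11 of 15 fell adjusted over the list alone, while the median of the fibroblast list turned to 0.08 with median centring. Against all other genes the adjusted p was 3.99e-15 (1.21e-19 to 0.000249 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. Weaker probes of Fn1 and Col5a1 read as little as -0.23 and -0.21.

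Of 18 elastic fibre genes, 10 fell adjusted over the list alone and 0 over all genes, with medians of -0.24, -0.53 and -0.39. Elastin itself, Eln, read -1.06 ± 0.51, Efemp2 -0.80 ± 0.29, Loxl3 -0.57 ± 0.18 and Fbln1 -0.40 ± 0.12 (SD, n = 3 each), and Fbln1 turned to 0.04 with median centring. Smooth muscle genes had medians of -0.36, -1.13 and -0.79 in the same samples and adventitial fibroblast markers -0.28, -0.42 and -0.32, the latter list turning to 0.08 with median centring. In camera the adjusted p was 3.82e-05 (5.9e-06 to 0.14 over 17 alternatives), and adjusted p = 0.396 with an estimated correlation. Median centring ended the call, at an adjusted p of 0.14.

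Matrix proteases and their inhibitors had medians of -0.13, -0.49 and -0.34. Of 24 unsaturated members, 10 fell and 1 rose adjusted over the list alone, and 0 passed over all genes. The stromelysin gene Mmp3 read -1.38 ± 0.58, Timp1 -0.73 ± 0.30 and Mmp2 -0.61 ± 0.21 (SD, n = 3 each). The 1 that rose was the cathepsin S gene Ctss, at 1.17 ± 0.53, with 0.78, 0.96 and 1.77, and named after its values were seen. In these samples the medians were -0.36, -1.13 and -0.79 for smooth muscle, -0.28, -0.42 and -0.32 for adventitial fibroblasts (0.08 for that list with median centring) and 0.16, 1.5 and 1.86 for lymphocyte markers. For the list, camera gave an adjusted p of 4.46e-06 (6.22e-09 to 0.0643 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. Median centring ended the call, at 0.0643.

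In TGF-beta signalling, 7 of 27 members fell adjusted over the list alone and 0 over all genes, with medians of -0.16, -0.38 and -0.12. Ccn2, a connective tissue growth factor, read -1.40 ± 0.62, the ligand gene Tgfb2 -1.08 ± 0.34, the activin subunit gene Inhba -0.93 ± 0.46 and Ltbp1 -0.79 ± 0.37 (SD, n = 3 each). A second, weaker probe of Ltbp1 read -0.11. Medians of smooth muscle genes (-0.36, -1.13 and -0.79) and of adventitial fibroblast markers (-0.28, -0.42 and -0.32, with the list at 0.08 under median centring) were likewise lowest in sample 2. Camera gave an adjusted p of 1.31e-05 (1.02e-06 to 0.691 over 17 alternatives), and adjusted p = 0.396 with an estimated correlation. The list's median turned to 0.09 with median centring, which ended the call.

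RhoA and myosin phosphatase signalling sets smooth muscle tone. Of its 27 members, 2 fell adjusted over the list alone and 0 over all genes, with medians of -0.08, -0.11 and -0.20. The 2 were Rnd3 at -0.70 ± 0.26 and Arhgef2 at -0.54 ± 0.10, while Ppp1r14a read -0.73 ± 0.38 and Limk1 0.51 ± 0.24 (SD, n = 3 each). Further probes of Arhgef2 read -0.01, -0.41 and -0.15. Rnd3, Arhgef2 and Ppp1r14a were lowest in sample 2, as smooth muscle genes were (medians of -0.36, -1.13 and -0.79), while the RhoA list's median was lowest in sample 3. Against all other genes the adjusted p was 0.004 (2.01e-05 to 0.582 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. The median turned to 0.23 with median centring, which ended the call.

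Of 29 unsaturated renin-angiotensin, endothelin and adrenergic genes, 0 passed in limma over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 were 7 of the 29, against 17.7% of all unsaturated features. The medians were -0.10, 0.0036 and -0.22. The lowest p-values were those of the cyclic nucleotide pathway genes Pde5a (-0.64 ± 0.27), Pde3a (-0.63 ± 0.28), Prkg1 (-0.55 ± 0.28) and Npr1 (-0.45 ± 0.19; SD, n = 3 each). Each of these was lowest in sample 2, as smooth muscle genes were (medians of -0.36, -1.13 and -0.79), while the list's own median was lowest in sample 3. In camera the adjusted p was 0.00985 (0.000783 to 0.699 over 17 alternatives), and adjusted p = 0.396 with an estimated correlation. The call ended without sample 3, at an adjusted p of 0.3, with array weights and with median centring, where the median turned to 0.13.

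Smooth muscle ion channel and calcium handling genes had medians of -0.08, -0.15 and -0.13. Of 27 members, 0 passed in either adjustment, and 9 were at an unadjusted p under 0.05. Abcc9, a subunit of ATP-sensitive potassium channels, read -0.78 ± 0.35, its partner Kcnj8 -0.33 ± 0.09 and Trpm4 -0.39 ± 0.13 (SD, n = 3 each), with Kcnj8 at 0.15 under median centring. For the list, camera gave an adjusted p of 0.00225 (0.000158 to 0.956 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. The list's median turned to 0.15 with median centring, which ended the call.

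Mitosis and cytokinesis genes were shifted upward, most in sample 3. Their medians were 0.15, 0.18 and 0.64, and 23 of 30 members were positive on every array, though 0 passed in either adjustment, with 12 at an unadjusted p under 0.05. Cdca8 read 0.55 ± 0.32, Incenp 0.46 ± 0.23 and Fzr1 0.25 ± 0.06, whereas the phosphatase gene Cdc25b read -0.64 ± 0.20 (SD, n = 3 each). Further probes of these genes read otherwise: -0.03 for Fzr1, -0.09 and 0.16 for Cdca8, and -0.15 and 0.07 for Cdc25b. The lymphocyte markers were also highest in sample 3, at 1.86. Camera gave an adjusted p of 7.13e-05 (9.17e-06 to 0.588 over 17 alternatives), and adjusted p = 0.522 with an estimated correlation, and median centring ended the call at 0.588.

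DNA replication genes had medians of 0.05, 0.14 and 0.30, with 0 of 24 members past either adjustment and 9 at an unadjusted p under 0.05. Mcm5 read 0.64 ± 0.35, Pcna 0.38 ± 0.19, Rfc3 0.31 ± 0.04 and E2f1 0.26 ± 0.04 (SD, n = 3 each). A second, weaker probe of E2f1 read 0.04. Lymphocyte markers were also highest in sample 3, with medians of 0.16, 1.5 and 1.86. Against all other genes the adjusted p was 0.0219 (0.000951 to 0.289 over 17 alternatives), and adjusted p = 0.522 with an estimated correlation. The call ended without sample 3 (0.289) and with median centring (0.0928).

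p53 targets and senescence genes showed no shift that passed. Their medians were -0.012, -0.01 and 0.11, and 0 of 21 unsaturated members passed in either adjustment, with 2 at an unadjusted p under 0.05. Perp read -0.65 ± 0.50, Pmaip1 0.61 ± 0.60, Gdf15 0.22 ± 0.09 and Bax -0.09 ± 0.04 (SD, n = 3 each), with Bax at 0.30 under median centring. In camera the adjusted p was 0.764 (0.247 to 0.992 over 17 alternatives). The list's median and mean lay above 0 while the test's direction was downward.

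Interferon response genes had medians of 0.59, -0.07 and 0.38, and 0 of 26 passed in either adjustment, with 7 at an unadjusted p under 0.05. The immunoproteasome gene Psmb8 read 0.77 ± 0.45, Usp18 0.50 ± 0.19 and Irf9 0.36 ± 0.20, while Rsad2 read -0.82 ± 0.43 (SD, n = 3 each). A second, weaker probe of Irf9 read 0.02. For the list, camera gave an adjusted p of 0.0019 (2.43e-08 to 0.148 over 17 alternatives), and adjusted p = 0.522 with an estimated correlation. The call ended without sample 1 (0.14), with array weights (0.148) and with median centring (0.0643).

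Of 25 inflammatory cytokine and adhesion genes, 2 fell adjusted over the list alone, Saa3 (-0.62 ± 0.08) and the prostaglandin synthase gene Ptgs2 (-0.51 ± 0.06), and 0 passed over all genes. The interferon-induced chemokine gene Cxcl10 read 1.04 ± 0.56 and Tnf 0.31 ± 0.07 (SD, n = 3 each). The medians were 0.13, -0.00036 and 0.21. Camera gave an adjusted p of 0.347 (0.0803 to 0.828 over 17 alternatives).

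Among 21 unsaturated immediate early and heat shock genes, Ccn1 fell and the AP-1 gene Junb rose (0.52 ± 0.10) adjusted over the list alone, and Ccn1 alone of these passed over all genes. Hspa1a read -0.64 ± 0.42 and Klf6 -0.32 ± 0.17 (SD, n = 3 each), with Klf6 at 0.15 under median centring. The medians were -0.21, -0.013 and -0.26. Against all other genes the adjusted p was 0.00769 (0.00014 to 0.928 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. The call ended without sample 1 (0.0559), without sample 3 (0.058), with array weights (0.0734) and with median centring, where the median turned to 0.20.

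Energy metabolism genes were too bright to be measured in most cases. Of 32 respiratory chain genes, 26 had a saturated spot, and all 21 that passed over all genes were among these. The 6 others had medians of 0.16, 0.08 and -0.10, with 0 past either adjustment and 1 at an unadjusted p under 0.05. They included Sdha (0.32 ± 0.10), Atp5d (0.14 ± 0.02) and Ndufv2 (0.05 ± 0.10; SD, n = 3 each), where Ndufv2 read -0.02 under Agilent's own log ratio. Both further probes of Sdha, the member at an unadjusted p under 0.05, had the other sign, at -0.03 and -0.04. The list's adjusted p of 1.22e-23 (3.06e-25 to 0.45 over 17 alternatives), adjusted p = 0.213 with an estimated correlation, became 0.45 with a median of 0.05 once saturated features were left out.

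Markers of white fat and brown fat were often saturated. Among 19 white fat markers 11 were saturated, including Adipoq, Fabp4 and Plin1, and all 8 calls over all genes were among them. The 8 other white fat markers had medians of 0.0063, 0.20 and -0.47, and 0 passed, with 0 at an unadjusted p under 0.05. Among them were Lipe at 0.17 ± 0.12, Pparg at 0.14 ± 0.16, Adrb3 at -0.40 ± 0.45 and Retn at -0.48 ± 0.79 (SD, n = 3 each), the last at 0.0065 under median centring. Further probes of Lipe read -0.0082 and -0.00018. The thermogenic genes Ucp1, Cox7a1 and Cox8b were saturated in both dyes on all arrays. The 5 brown fat calls over all genes were all on saturated probes. The 11 unsaturated brown fat markers had medians of -0.18, 0.16 and 0.08, with 0 past either adjustment and 0 at an unadjusted p under 0.05. Of these, Otop1 read 0.12 ± 0.30, Zic1 0.08 ± 0.21, Kng1 -0.22 ± 0.52 and Prdm16 -1.02 ± 1.69, with Zic1 above background in Cy3 on 0 arrays. With median centring the brown fat median over all members turned from -0.03 to 0.35 (camera adjusted p 0.106). Both lists lost their calls (adjusted p 1.86e-10 and 0.000328) without saturated features, at 0.45 and 0.549. Over 17 alternatives their adjusted p ran from 2.05e-13 to 0.45 and from 1.71e-05 to 0.549. The white and brown fat lists had adjusted p = 0.251 and adjusted p = 0.341 with an estimated correlation.

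Of the oxidative stress and NADPH oxidase genes, 3 passed over all genes, all saturated, and 0 of 22 unsaturated members passed adjusted over the list alone, with 7 at an unadjusted p under 0.05. Cybb read 0.67 ± 0.36, Cyba 0.40 ± 0.14, Txn1 0.29 ± 0.06 and Nqo1 -0.47 ± 0.21 (SD, n = 3 each), and a second probe of Cybb read -0.05. The medians were 0.00041, 0.04 and -0.02. The adjusted p of 0.0272 (0.0151 to 0.828 over 17 alternatives), adjusted p = 0.341 with an estimated correlation, became 0.733 without saturated features, where the median was -0.02 and the mean 0.04. The call ended under 10 of 17 alternatives, among them the data without sample 1 (0.0862) and without sample 3 (0.164), and the median over all members turned from -0.09 to 0.37 with median centring.

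Markers of other cell types differed between samples. Lymphocyte markers had medians of 0.16, 1.5 and 1.86, and 15 of 18 were positive on every array. The T cell receptor component gene Cd3d read 1.79 ± 1.22, Coro1a 1.34 ± 0.80, Ptprc, the common leukocyte antigen CD45, 1.32 ± 0.87 and Ccr7 1.22 ± 0.82 (SD, n = 3 each). In either adjustment limma called 0 of the 18, with 12 at an unadjusted p under 0.05. For the list, camera gave an adjusted p of 1.6e-06 (1.34e-14 to 0.023 over 17 alternatives), and adjusted p = 0.396 with an estimated correlation. Sample 2, with the lowest smooth muscle median, and sample 3 both had high lymphocyte medians.

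Skeletal muscle markers were lowest in sample 3, with medians of -0.75, -0.89 and -2.70, and heart muscle markers had medians of -0.76, -0.11 and -2.19. Among them Eno3 read -1.61 ± 0.86, the sarcoplasmic calcium pump gene Atp2a1 -1.56 ± 1.03, Acta1 -1.31 ± 0.86 and Casq1 -1.18 ± 0.66 (SD, n = 3 each). Of the heart list, Myh7 read -1.90 ± 1.31, Mybpc3 -1.68 ± 1.23, Actc1 -0.86 ± 0.63 and Myl3 -0.80 ± 0.54. A second, weaker probe of Myl3 read -0.19, and that of Myh7 -1.96. Of the 15 and 19 unsaturated members, 0 passed in either adjustment, with 12 and 9 at an unadjusted p under 0.05. Camera's adjusted p-values were 2.59e-09 (3.81e-16 to 7.73e-06 over 17 alternatives) and 1.82e-06 (5.57e-15 to 0.000361), and each list had adjusted p = 0.396 with an estimated correlation.

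Adventitial fibroblast markers were lower by a similar amount in each sample, with medians of -0.28, -0.42 and -0.32. Of 15 unsaturated members, 11 fell adjusted over the list alone and 0 over all genes, among them Col14a1 (-0.55 ± 0.24), Mfap5 (-0.54 ± 0.23) and Entpd2 (-0.48 ± 0.20; SD, n = 3 each), with Entpd2 at 0.0025 under median centring. The elastic fibre list also holds Fbln1 and Mfap5 and the matrix list Col14a1, and a second probe of Col14a1 read -0.08. Camera gave an adjusted p of 1.11e-06 (4.62e-07 to 0.828 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation. The median turned to 0.08 with median centring, which ended the call.

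Endothelial markers lay near 0, with medians of 0.03, -0.02 and -0.18 and 0 of 15 past either adjustment, with 2 at an unadjusted p under 0.05. Flt1 read -0.40 ± 0.22, Nos3, the endothelial nitric oxide synthase gene, -0.33 ± 0.09, Kdr -0.15 ± 0.10 and Esam -0.15 ± 0.07 (SD, n = 3 each), and under median centring the 4 read 0.09, 0.05, 0.31 and 0.27. Further probes of Flt1 read from -0.19 to 0.27. Against all other genes the adjusted p was 0.0387 (0.0107 to 0.521 over 17 alternatives), and adjusted p = 0.522 with an estimated correlation. The call ended under 8 of 17 alternatives, among them the data without sample 3 (0.521), and the median turned to 0.39 with median centring (0.039).

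Macrophage markers had medians of -0.06, -0.13 and 0.17, and 0 of 17 unsaturated members passed in either adjustment, with 7 at an unadjusted p under 0.05. Cd163 read -0.40 ± 0.22, Pf4 -0.37 ± 0.18, Cd14 -0.34 ± 0.07 and F13a1 -0.29 ± 0.05 (SD, n = 3 each), of which Cd163, Pf4 and F13a1 read 0.01, 0.10 and 0.16 under median centring. These had the lowest p-values, while 10 of the 17 had means above 0. Named after their values were seen, Aif1 read 0.87 ± 0.65, Tyrobp 0.37 ± 0.29 and Fcer1g 0.27 ± 0.17, each at an unadjusted p under 0.05. In camera the adjusted p was 0.29 (0.0916 to 0.976 over 17 alternatives). The list's median was 0.02 and its mean -0.01 over all members, and 0.04 and 0.03 over the 17 unsaturated members.

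Red cell and granulocyte markers had medians of -0.14, -0.45 and -0.35. Of 13 unsaturated members, 4 fell adjusted over the list alone, and Slc4a1 was the 1 that passed over all genes. The haem synthesis gene Alas2 read -0.91 ± 0.44 and Bpgm -0.48 ± 0.22 (SD, n = 3 each), while the globin genes Hba-a1 and Hbb-bt were saturated. For the list, camera gave an adjusted p of 3.72e-06 (2.62e-10 to 0.000209 over 17 alternatives), and adjusted p = 0.341 with an estimated correlation.

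Schwann cell and nerve markers had medians of 0.58, 0.43 and -0.04. The myelin genes Cnp (0.55 ± 0.13) and Mbp (0.45 ± 0.08) rose adjusted over the list alone, and 0 of 16 unsaturated members passed over all genes. Ncmap read 0.30 ± 0.36 (SD, n = 3 each). Camera gave an adjusted p of 0.0219 (9.89e-05 to 0.483 over 17 alternatives), and adjusted p = 0.522 with an estimated correlation. The call ended without sample 1 (0.483) and with median centring (0.131).

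Of 10 markers of lymph node stroma, oesophagus and airway epithelium, the keratin gene Krt18 fell (-0.62 ± 0.02) over all genes and adjusted over the list alone. The B cell chemokine gene Cxcl13 read 1.28 ± 1.36, Tff2 0.20 ± 0.06 and Krt14 -0.16 ± 0.14 (SD, n = 3 each), with Tff2 at -0.17 and Krt14 at 0.07 under median centring. Tff2 was above background in Cy3 on 0 arrays, so its ratio is not one of 2 measured signals. The medians were -0.11, -0.0036 and 0.01. Against all other genes the adjusted p was 0.405 (0.131 to 0.972 over 17 alternatives), with a list mean of 0.07 and a downward direction of the test.

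**Figure D3:**
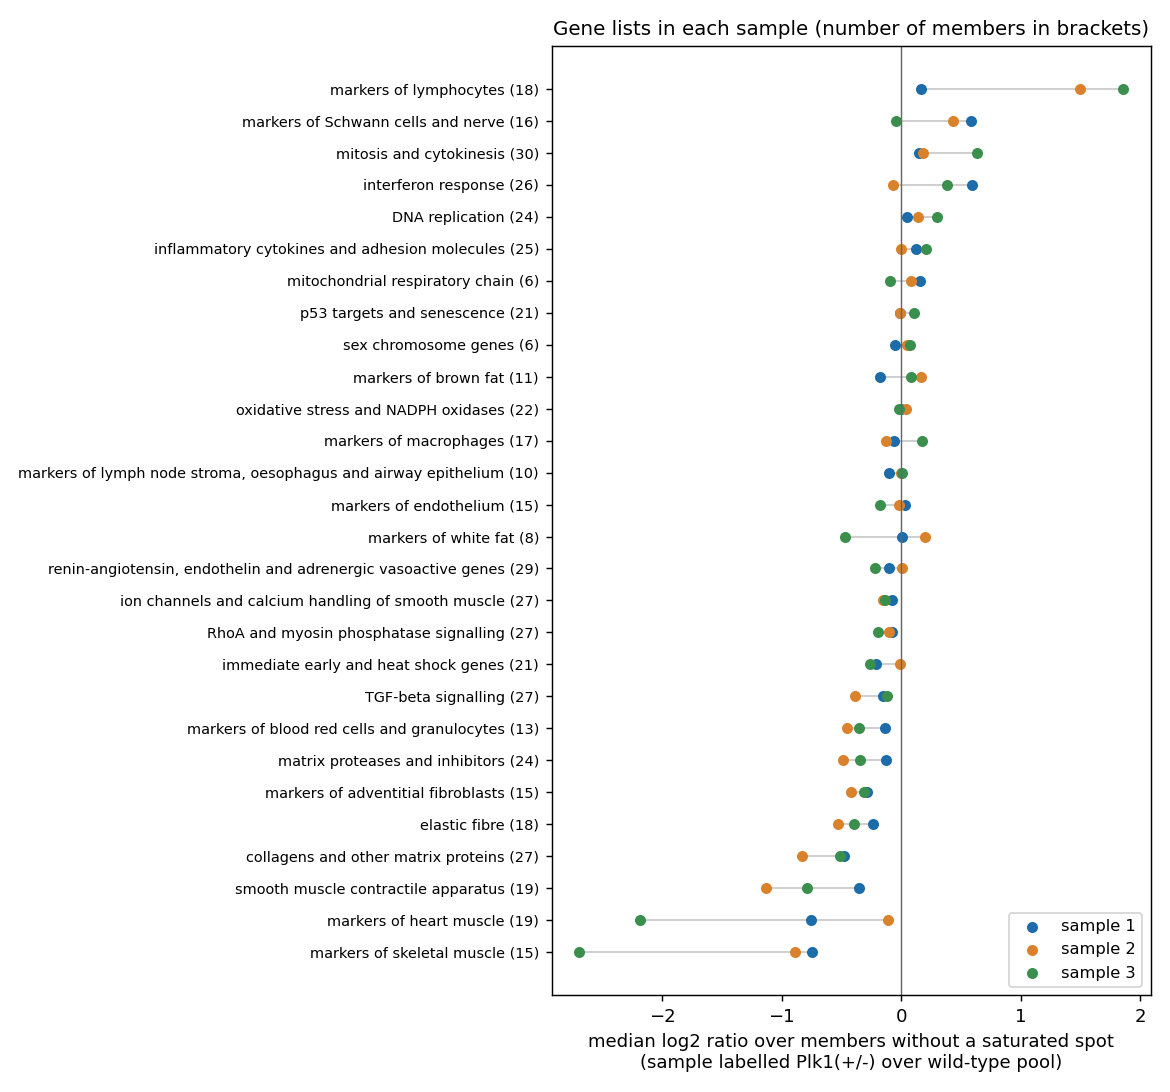
Median log2 ratio of each gene list (horizontal axis) in each of the 3 samples (points), over the members without a saturated spot, whose number is in brackets. Grey lines span the 3 samples. Smooth muscle medians lie between -1.13 and -0.36, lymphocyte medians between 0.16 and 1.86 and skeletal muscle medians between -2.70 and -0.75.

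Sex chromosome genes showed no difference that passed. Of 6 measured genes, 0 passed in either adjustment and 0 had an unadjusted p under 0.05, with medians of -0.06, 0.04 and 0.08. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d, Uty and Zfy1 had means of 0.21 ± 0.22, 0.09 ± 0.16, -0.04 ± 0.02, -0.06 ± 0.21 and -0.13 ± 0.08, and Xist a mean of -0.04 ± 0.21 (SD, n = 3 each). Kdm5d turned to 0.11 with median centring, Zfy1 to 0.03 with the mean of its probes, and Xist to 0.15 under Agilent's own log ratio. Xist was above background on 2 arrays in Cy5 and 1 in Cy3, so its ratio says little about balance. Further probes of Ddx3y and Zfy1 had the other sign, at -0.0062 and 0.18.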

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

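The alternatives without saturated features were chosen after the data were seen, the others before the data were examined. The 204 calls (8 higher, 196 lower) became 116 with Agilent's own log ratio (110 lower), 433 with array weights (56 higher, 377 lower), 9813 with median centring (7169 higher, 2644 lower), and 0 with an intensity trend (0 higher, 0 lower) and without saturated features (0 higher, 0 lower). They became 62 at a threshold of 0.01 (0 higher, 62 lower) and 372 at 0.1 (50 higher, 322 lower). The mean of a gene's probes left 5 higher, and a log2 change of at least 1 left 3 higher. Leaving out 1 sample gave between 0 and 175 calls (0 to 57 higher, 0 to 118 lower), with fewer samples behind each test. Leaving out saturated features takes 172 small p-values out of the adjustment. The other causes were not tested. The 32 called features without a saturated spot kept their sign under all 16 alternatives that compared them by gene, and between 0 and 32 of them stayed called. These features were picked for a mean that was large against its spread, so a kept sign adds no support. An intensity trend and leaving out saturated features do not alter their ratios at all.

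The 23 called lists became 9 with median centring (8 in the same direction), 5 with fry, 0 with an estimated correlation and 0 with an estimated correlation without saturated features. Leaving out 1 sample gave 18 to 23 lists.

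Median centring keeps each array's dye curve with brightness, and raised the median of all features from 0.04 to 0.23. It turned the list medians, taken over all members, of RhoA signalling (0.23), TGF-beta signalling (0.0923), immediate early genes (0.20), ion channels (0.15), adventitial fibroblasts (0.0843), brown fat (0.35), endothelium (0.39), oxidative stress (0.37) and vasoactive genes (0.13). It also turned Bax (0.30), Cd163 (0.0139), Entpd2 (0.0025), Esam (0.27), F13a1 (0.16), Fbln1 (0.0436), Flt1 (0.0867), Kcnj8 (0.15), Kdm5d (0.11), Kdr (0.31), Klf6 (0.15), Kng1 (0.22), Krt14 (0.0745), Nos3 (0.0525), Pf4 (0.10), Retn (0.0065), Tff2 (-0.17) and Zic1 (-0.52).

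Elsewhere values near 0 changed sign, with causes not tested: Ndufv2 (-0.0241) and Xist (0.15) under Agilent's own log ratio and equally in the authors' series table, Xist (0.0465) and Zic1 (-0.0081) with array weights, Zfy1 (0.0259) with the mean of its probes, and the list of lymph node stroma, oesophagus and airway epithelium (0.0164) with either other filter on dim probes. The respiratory chain list turned to 0.0481 without saturated features. Leaving out 1 sample gave means on both sides of 0 for Uty (-0.182 to 0.0116), Zic1 (-0.0221 to 0.189), Otop1 (-0.0358 to 0.267), Kng1 (-0.378 to 0.0803), Plk1 (-0.0678 to 0.183) and Xist (-0.136 to 0.0694), and medians on both sides of 0 for the list of lymph node stroma, oesophagus and airway epithelium (-0.0478 to 0.0038) and the macrophage list (-0.109 to 0.0347). Signal over background limits dim genes such as Zic1, above background in Cy3 on 0 arrays, and saturation limits the brightest.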

Other observations

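Each test of an explanation in this part was chosen after the result was seen, and the gene groups of the first paragraph were drawn up after their values were seen.

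Samples differed in genes of other tissues. Genes of autonomic neurons were highest in sample 1, with medians over 20 unsaturated genes of 1.87, 0.76 and -0.35 in samples 1, 2 and 3. The neuropeptide genes Vip and Cartpt read 2.68 and 2.05 in sample 1 and -0.65 and -0.40 in sample 3. Genes known from liver had medians of -2.05, 0.95 and -1.07 over 14 genes, with Alb at -2.45, 1.56 and -2.40 and Mup1 at -3.72, -0.69 and -3.85. The atrial myosin light chain gene Myl7 read -4.06, 0.54 and -4.10. The macrophage scavenger receptor gene Marco read -1.10, 3.48 and 4.90, and Glycam1, a ligand on lymph node venules, -1.18, 2.52 and 3.85, with Cy5 above background on 2 arrays only. Ratios of different arrays share the pool. Over unsaturated features they correlated at 0.35 (samples 1 and 2), 0.21 (1 and 3) and 0.54 (2 and 3), against 0.25 simulated without any difference, with covariances of 0.04, 0.03 and 0.09 against 0.04. These correlations are across genes, which are not independent replicates. The simulation drew independent noise of equal spread for each gene, with a pool of 3 and without array noise or a dye effect. The 0.25 follows from that setting alone, so it is not a baseline for these arrays.

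The 172 calls on probes with a saturated spot may come from the Cy5 channel reaching the scanner's limit. Where both dyes were saturated on all arrays, the raw log2 ratio was 0.00044. The lower value of those features thus came from the normalization and not from a measured difference. Of the 159 genes with a symbol behind these calls, 42 had unsaturated second probes above background in both dyes on all arrays, 56 probes in all. These had a median log2 ratio of -0.00017 and an upper quartile of 0.0625, against a median of -1.24 on the saturated probes of the same genes. A lower RNA level of these genes would have put the second probes below 0 as well, and their lower quartile was -0.16. Lower RNA therefore does not account for the calls of these 42 genes as a set, and the other genes could not be checked this way.

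Smooth muscle contractile genes were lower in each sample, by different amounts. Sample 2 minus sample 1 had a median of -0.79 over the 19 members (quartiles -1.04 and -0.42), with 18 below 0, and a dye effect fixed for each probe or the shared pool would enter all arrays alike, so neither accounts for this part, though a dye effect that varies between arrays was not tested. A smaller share of aortic wall, with other tissues in fixed proportion, would raise their markers alike. In sample 2 medians of 6 other marker lists lay up to 2.39 apart, from skeletal muscle at -0.89 to lymphocytes at 1.5. That spread is over the pool, and skeletal muscle was already at -0.75 in sample 1. From sample 1 to sample 2 the lymphocyte median went from 0.16 to 1.5. The others moved less, endothelium from 0.03 to -0.02, macrophages from -0.06 to -0.13 and white fat from 0.0063 to 0.20. Schwann cell and nerve markers went from 0.58 to 0.43. Between these samples the lymphocyte list alone thus stood against this explanation. For the part common to all samples, where the median over members of the highest of the 3 ratios was -0.36, dye, pool and genotype cannot be told apart, since no array had swapped dyes. Tissues taken in different amounts at once also stay open, with endothelial markers at -0.018 in sample 2. A genotype effect of equal size in all 3 samples would likewise not give the part that differs between them. One that varies between samples stays open and untested.

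Lymphocyte markers were higher in samples 2 and 3 and striated muscle markers lowest in sample 3. Sample 3 minus sample 1 had a median of 1.72 over the lymphocyte markers (quartiles 1.22 and 2.26) and of -1.90 over the skeletal muscle markers (quartiles -2.23 and -1.65), which a fixed dye effect or the shared pool would not give. Lymph node tissue carried along with samples 2 and 3 is a candidate source for the first. A group of venule and stroma genes, drawn up after the values were seen, held 3 measured genes that lymphocytes do not make, other than Glycam1 and Marco. Their median difference was 0.32. In samples 1, 2 and 3 Cxcl13 read -0.29, 2.04 and 2.09, Chst4 0.05, -0.18 and 0.15, and Madcam1 -0.24, -0.12 and 0.08. These are too few to decide, and Madcam1 was above background in Cy3 on 0 arrays. Outside that group, the chemokine gene Ccl19 read -0.35, 1.32 and 1.34, and was named after its values were seen. A genotype effect on leukocytes of equal size in all 3 samples would not give the differences between samples either. One that varies between samples stays open and untested.

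Plk1 lay below the median of the mitosis genes in each sample, with differences of -0.21, -0.26 and -0.21. A hypothesis is that Plk1 RNA was lower per dividing cell. Against that, 4 of the 30 mitosis genes lay as far below the median on all 3 arrays, so Plk1 did not stand apart, and this cannot be decided here.

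A segment of another strain kept around the targeted allele could leave neighbouring genes changed. The 20 measured genes on either side of Plk1 had, with it, a mean absolute log2 ratio of 0.14, and 87.1% of 15883 windows of that many genes across the genome had one as large. The neighbours thus did not stand out as a group. A mean over that many genes cannot show a change in a few of them, so a segment that alters few genes stays open.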
